A study of Homo sapiens with 8 samples.

How the data were processed

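Single-nucleus RNA sequencing was performed on cells that stuck to acupuncture needles at the acupoint BL23, on the lower back, in people with low back pain. By the numbers in the titles, the 8 libraries came from 4 donors, 2 with chronic and 2 with acute pain, each sampled at week 0, before treatment, and at week 2, after acupuncture given 2 times per week. Per the labels, nuclei were isolated from snap-frozen material and libraries were made with a 10x Genomics 3' kit. Per the submitters' processing notes, the reads were processed with Cell Ranger 7.2.0 on GRCh38, while the matrix headers name version 7.1.0. The deposited values are raw counts of unique molecular identifiers (UMIs) per gene and barcode, with no normalization, and the rule by which barcodes were selected before deposit is not given in the sources used here.

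The matrices held 36601 genes. Genes that could mark a person (those of the Y chromosome, the RNA of X inactivation and its antisense, genes often deleted in the germline, and immunoglobulin and T-cell receptor segments; 782 genes) were left out of every table of genes, leaving 35819. Other genes of the X chromosome stayed in. Barcodes with 200 to 6000 detected genes and at most 10% mitochondrial UMIs were kept as nuclei, which left 113389 of 235370 barcodes. No doublet caller was run, so doublets remain in all classes. Totals per library ranged from 297154 to 37817862 UMIs as deposited and from 24533 to 35973263 UMIs in kept nuclei, so 1 UMI was worth between 0.0358 and 27.0 CPM (UMIs scaled by library size and TMM factor). Intervals of shares are 95% Wilson intervals, and limits for a share of 0 use 3 counts. They cover counting error only.

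Donors, not nuclei, were the replicates. UMIs were summed per library and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter over the 4 groups (15692 genes tested) and Benjamini-Hochberg adjustment at 0.05. Changes after treatment were fitted with the donor as a block over all 8 libraries, and differences between conditions with 4 group means and no block. The standard error (SE) of a log2 fold change is its size divided by the square root of the F statistic. The groups, the tests, the alternatives, the gene lists, the class markers and the rule for named genes were fixed before the data were examined. By that rule, the 12 genes of smallest p each way were named for treatment among those past the threshold that moved the same way in all 4 pairs. Up to 10 genes each way were named between conditions if the groups did not overlap, up to 10 for the difference of changes, and up to 4 members of each gene list. Where too few genes passed, further genes were filled in by p and are given as values. Some genes that the rule names are not reported here.

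The pairing rests on the donor number in the titles and on the series design, which describes the collections as paired. Deviations from the group means correlated within pairs with r = 0.073 in chronic and r = 0.119 in acute donors. A check for mixed-up samples found that the libraries of 1 of 4 pairs did not match each other. That pairing is uncertain, and every value per pair or with the donor as a block carries this limit. Replicates of a group differed by more than sampling noise (chi-square per degree of freedom 2.60 to 46.2), so none was counted as a duplicate. The labels name no batch.

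Kept nuclei were clustered together with scanpy 1.11.5 (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.5, no integration). A cluster received a class name when at least 3 and at least 40% of the fixed markers of a type were raised by a log2 fold of 1 or more, and no library held over 90% of it. These thresholds were set after the clusters had been seen. The planned test of treatment within a class needed 20 nuclei in both libraries of at least 3 donors, and no class had more than 2 such donors. Fits within classes over fewer donors, lists tested within each condition, and fits without the acute libraries after treatment were added after seeing the data. Class shares were compared with an exact sign-flip permutation test of their logits over 4 pairs, in which 0.125 is the smallest two-sided p.

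The 24 gene lists were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over the lists), with an estimated correlation and fry as alternatives. The procedure was tested on simulated data with 200 changed genes. For treatment over all donors it recovered 3, 32 and 64 genes (4.5%, 47.8% and 97.0%) of those changed by log2 1, 2 and 3. It made 10 false calls there among 15279 genes. Within chronic donors it recovered 3, 27 and 58 (4.5%, 40.3% and 87.9%), against 13 false calls among 15251 genes. Within acute donors it recovered 0, 1 and 16 (0%, 1.5% and 24.2%), against 2 false calls among 15211 genes. For chronic against acute before treatment it recovered 3, 40 and 60 (4.5%, 59.7% and 90.9%), against 16 false calls among 15222 genes. In each of these comparisons false calls made up a larger share of all calls than the threshold of the adjustment allows on average. The changed genes were drawn from the more abundant ones, and all simulated libraries shared the same gene proportions. Recovery may thus be lower for scarcer genes and for donors that differ. A list shifted by log2 2 reached a camera adjusted p of 2.31e-36, and 1 of the 23 other lists was called. Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, at least 500 genes per nucleus, no mitochondrial limit, all deposited barcodes, libraries thinned to 24496 UMIs, no block, and each donor or library left out in turn. The main fits tested 15692 genes. Thinning left 486 to test, at least 500 genes per nucleus 11000, all deposited barcodes 22894 and no low-count filter 33307. Counts under these settings thus have other denominators.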

Results

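The data comprised 8 single-nucleus libraries in 4 groups of 2: chronic pain before and after treatment (replicates 1 and 2) and acute pain before and after treatment (replicates 3 and 4). Depth differed widely between libraries. Before treatment, chronic replicates 1 and 2 held 701 and 48666 barcodes with 297737 and 15647241 UMIs. Acute replicates 3 and 4 held 87710 and 6612 barcodes with 37817862 and 3813470 UMIs. After treatment, chronic replicates 1 and 2 held 151 and 6958 barcodes with 297154 and 2828062 UMIs. Acute replicates 3 and 4 held 60349 and 24223 barcodes with 2875206 and 1975463 UMIs. The filters kept 442, 20552, 151 and 5127 nuclei in the chronic libraries, in the order week 0 then week 2, and 80450 and 6450 in the acute libraries before treatment. In the acute libraries after treatment only 79 and 138 nuclei were kept, because their deposited barcodes had medians of 40 and 76 UMIs against 236 to 1378 in the other 6 libraries. MALAT1, a long noncoding RNA retained in the nucleus, made up 0.182% and 0.210% of UMIs in those libraries and 1.11% to 2.30% in the others.

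**Figure D1:**
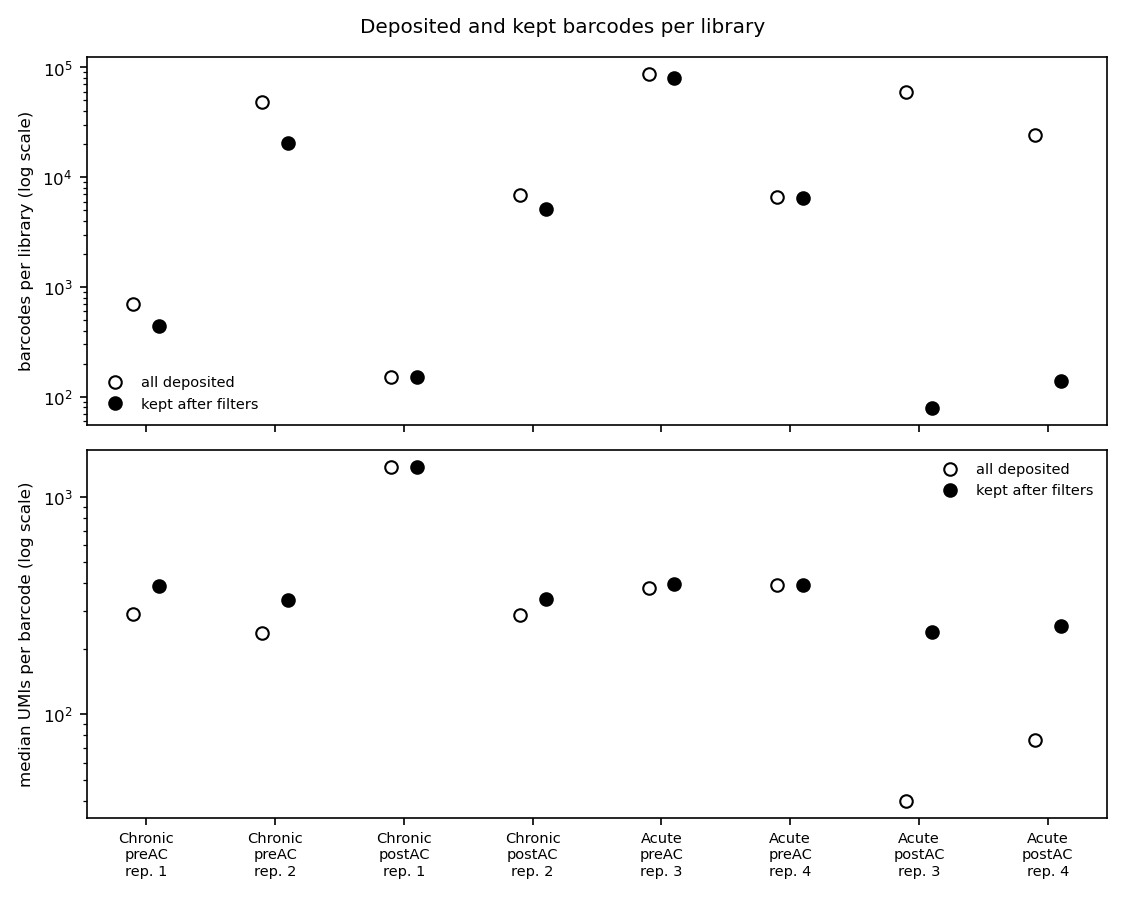
Barcodes per library (upper panel) and median UMIs per barcode (lower panel), both on log axes, for all deposited barcodes (open) and kept nuclei (filled). The acute libraries after treatment fall from 60349 and 24223 deposited barcodes to 79 and 138 kept nuclei.

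Clustering gave 10 clusters, of which 7 received a class name. Pericyte or smooth muscle-like nuclei were led by RGS6, CARMN and MYH11. Vascular endothelial-like nuclei were led by MECOM, ANO2 and PTPRB. Skeletal myonucleus-like nuclei were led by AGBL1, KCNQ5 and ARPP21. Macrophage or monocyte-like nuclei were led by F13A1 and RBM47, adipocyte-like nuclei by PDE3B and GPAM, and Schwann cell-like nuclei by XKR4. Fibroblast-like nuclei had 5 of 12 fixed markers raised, but none among their 10 leading genes, which opened with KIRREL3, KCNB2 and MEG8. Unnamed clusters held 81.4% of kept nuclei, above all cluster 0 (67599 nuclei, 97.0% from acute replicate 3 before treatment), whose leading genes S100A1, TCAP, DES and MYL2 are muscle genes. Cluster 1 (24517 nuclei) was led by COMP and by the keratinocyte genes KRT14 and DSP. Unnamed nuclei made up 21.5% and 60.8% of the chronic libraries before treatment and 7.95% and 2.09% after. They made up 96.1% and 31.8% of the acute libraries before and 98.7% and 84.8% after.

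The observed shares of pericyte or smooth muscle-like and myonucleus-like nuclei were lower after treatment in 4 of 4 pairs. Pairs here and below follow the numbers in the titles, and 1 of the 4 did not match in a check for mixed-up samples. In replicates 1 and 3 the share before lies inside the interval of the share after for both classes. Pericyte or smooth muscle-like nuclei went from 1.58% (95% Wilson interval 0.769 to 3.23) and 15.9% (15.4 to 16.4) to 0 of 151 nuclei, which allows up to 1.99%, and 1.42% (1.13 to 1.79) in chronic donors. In acute donors they went from 0.957% (0.892 to 1.03) and 10.6% (9.85 to 11.3) to 0 of 79 nuclei, which allows up to 3.80%, and 1.45% (0.398 to 5.13). Skeletal myonucleus-like nuclei went from 8.37% (6.13 to 11.3) and 4.74% (4.46 to 5.04) to 5.30% (2.71 to 10.1) and 0.0780% (0.0303 to 0.20) in chronic donors. In acute donors they went from 1.10% (1.03 to 1.18) and 6.54% (5.96 to 7.17) to 0 of 79 and 0 of 138 nuclei, which allows up to 3.80% and 2.17%. Cluster 0 had 6 of 14 myonucleus markers raised and failed the limit of 90% from 1 library. Its share went from 3.62% and 6.03% to 5.30% and 0.0975% in chronic replicates 1 and 2. In acute replicates 3 and 4 it went from 81.5% and 11.7% to 5.06% and 0.725%. The myonucleus-like shares, above all in acute replicate 3, thus depend on that limit. The mean logit change was −1.63 ± 0.888 (SD, n = 4 pairs) for pericyte or smooth muscle-like and −2.01 ± 1.78 (SD, n = 4 pairs) for myonucleus-like nuclei. Each had an exact permutation p of 0.125, the smallest that 4 pairs allow, and a Benjamini-Hochberg value of 0.4375 over 7 classes. With at least 500 genes per nucleus, which left 3 nuclei in each acute library after treatment, the mean changes were −0.871 and −0.648 (exact permutation p = 0.5 and 0.625).

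Other classes did not move one way. Fibroblast-like nuclei were 44.1% (39.6 to 48.8) and 5.81% (5.50 to 6.14) of the chronic libraries before treatment and 43.0% (35.4 to 51.0) and 84.5% (83.5 to 85.5) after. They went from 0.588% (0.537 to 0.643) and 31.7% (30.6 to 32.9) to 0 of 79 nuclei, which allows up to 3.80%, and 4.35% (2.01 to 9.16) in acute donors. Without replicate 2 their mean logit change turned from 0.563 ± 2.82 (SD, n = 4 pairs) to −0.743. Macrophage or monocyte-like nuclei went from 8.37% (6.13 to 11.3) and 2.10% (1.91 to 2.30) to 43.0% (35.4 to 51.0) and 6.34% (5.70 to 7.04) in chronic donors. In acute donors they went from 0.329% (0.292 to 0.371) and 2.08% (1.76 to 2.46) to 0 of 79 nuclei, which allows up to 3.80%, and 1.45% (0.398 to 5.13). The mean logit change over all pairs was 0.936 ± 0.944 (SD, n = 4 pairs; exact permutation p = 0.25), in which replicate 3 counts as a rise only through the 0.5 nucleus added to 0. Vascular endothelial-like nuclei were lower after treatment in 3 of 4 pairs (mean logit change −0.653 ± 1.10 SD, exact permutation p = 0.375). Adipocyte-like and Schwann cell-like shares were lower in 3 of 4 pairs each in percentage points, but on the logit scale in 2 of 4, since the 0.5 nucleus added to counts of 0 sets the sign there. Their mean logit changes were −0.513 ± 2.22 and −0.0665 ± 2.89 (SD, n = 4 pairs; exact permutation p = 0.875 and 1.0). Between conditions, 2 donors against 2 allow no exact test below 0.05, and only the values were compared.

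**Figure D2:**
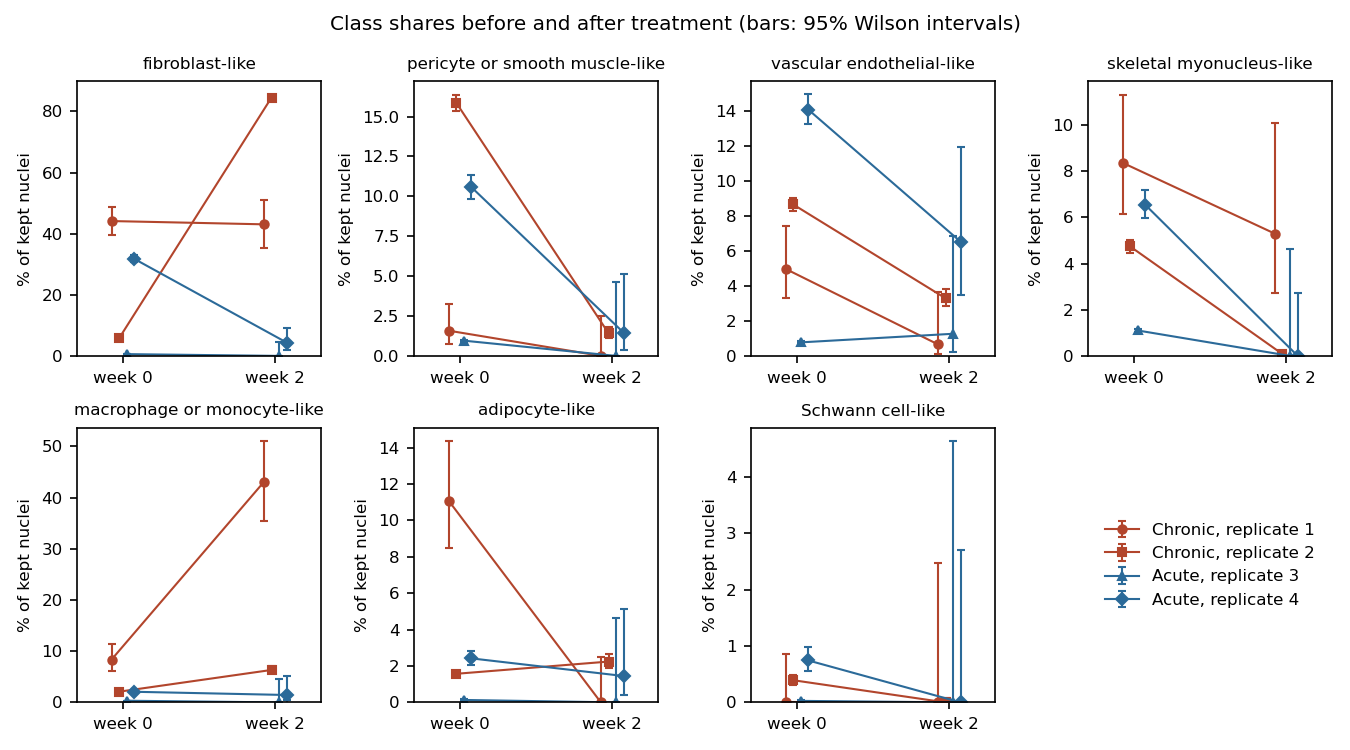
Share of kept nuclei in each named class at week 0 and week 2, one line per donor, chronic in red and acute in blue, with 95% Wilson intervals and a separate vertical axis per class. The observed pericyte or smooth muscle-like and skeletal myonucleus-like shares are lower at week 2 in 4 of 4 pairs, on 0 of 79 nuclei in acute replicate 3.

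Over all donors, the 41 of 15692 tested genes past the threshold after treatment all fell, and genes of muscle were among them. Falls included those of TBX2 (ENSG00000121068), a transcriptional repressor (log2 fold −4.06, SE 0.83, n = 4 pairs, edgeR Benjamini-Hochberg adjusted p = 0.00691) and of IGFN1 (ENSG00000163395), a protein of the muscle Z-disc (−3.79, SE 0.78). TBX2 went from 52.1, 155.3, 57.5 and 106.6 CPM to 0, 6.81, 0 and 38.3 CPM in replicates 1 to 4. Further falls were of S100A1, a calcium-binding protein of striated muscle (−3.48, SE 0.75), and PTP4A3, a phosphatase (−3.46, SE 0.75). PTGDS, a prostaglandin D synthase (−3.54, SE 0.78), and PYGM, the muscle glycogen phosphorylase (−3.31, SE 0.73), also fell. SYNPO, an actin-associated protein (−3.20, SE 0.71), and the muscle attachment proteins NRAP (−3.17, SE 0.71) and XIRP1 (−3.35, SE 0.76) fell as well. The matrix cross-linking enzyme TGM2 and HJV, a coreceptor of bone morphogenetic proteins, kept 2 UMIs each after treatment, and their pooled levels were 57.5-fold (95% counting interval 15.9 to 475) and 57.8-fold (16 to 478) higher before it. Here and below, pooled levels divide summed UMIs by summed depth without pairing, so the deepest libraries weigh most. Over all donors these were acute replicate 3 before (35973263 kept UMIs) and chronic replicate 2 after treatment (2431200). Counting intervals leave out the spread between donors.

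No gene passed as a rise. The naming rule admitted only genes higher in 4 of 4 pairs. Nearest to passing among these were DGKI, a diacylglycerol kinase (2.33, SE 0.63, edgeR Benjamini-Hochberg adjusted p = 0.0592), and MARCO, a macrophage scavenger receptor (2.07, SE 0.61). HMGA2, a chromatin protein (3.24, SE 0.98), the helicase gene BRIP1 (2.77, SE 0.90), the mitotic kinase gene MELK (2.31, SE 0.76) and GALNT13, a glycosyltransferase (1.72, SE 0.60), followed. In acute replicate 3 after treatment DGKI was at 80.9 and MARCO at 53.9 CPM, where 1 UMI was worth 27.0 CPM. ROR1-AS1 (2.39, SE 0.72) and HAS2-AS1 (1.92, SE 0.66) are antisense genes, and strand use in counting is not given in the sources used here, so both are uncertain.

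Among the fixed lists, slow muscle fibre genes stood lowest. None of 12 tested members passed over all genes and 11 were lower when adjusted over the list alone (median log2 −2.48, camera adjusted p = 3.84e-15, 0.44 with an estimated correlation), such as MYL3 (−2.58, SE 0.70) and the calcium store protein CASQ2 (−2.71, SE 0.75). Of 12 fast fibre genes, 1 fell over all genes, the kinase gene MYLK2 (−2.84, SE 0.72, edgeR Benjamini-Hochberg adjusted p = 0.0440), and 11 were lower when adjusted over the list alone (median −2.22, camera adjusted p = 2.63e-09, 0.44 with an estimated correlation). In the muscle injury and regeneration list 1 of 13 members fell and 6 were lower when adjusted over the list alone (median −1.5, camera adjusted p = 0.0421, 0.539 with an estimated correlation), among them CSRP3 (−2.52, SE 0.67). Camera also called lower medians for heat shock and unfolded protein response (−0.95, adjusted p = 2.81e-04), mitochondrially encoded (−0.70, 5.20e-05), lipid metabolism (−1.09, 0.00162), antigen presentation (−0.91, 0.00488), extracellular matrix (−0.75, 0.00498) and angiogenesis genes (−0.68, 0.0293). Their adjusted p with an estimated correlation lay between 0.44 and 0.58, and none of their members passed over all genes. Adjusted over the list alone, the lipid list had 2 lower members, PLIN1 (−2.96, SE 0.84) and FABP4 (−2.39, SE 0.79), the matrix list had 1, COL15A1 (−2.09, SE 0.66), and the other 4 had 0. Keratinocyte differentiation was called higher on 4 members (median 1.72, camera adjusted p = 0.0229, 0.44 with an estimated correlation), with 0 of 4 past the threshold. Camera did not call the lists of pain receptors and ion channels (median 0.11, adjusted p = 0.135), proinflammatory cytokines (−0.37, 0.266, direction up), neuropeptides, opioids and neurotrophins (0.13, 0.181, direction down), immediate early genes (−0.81, 0.412), interferon response (−0.36, 0.272), hypoxia and glycolysis (−0.81, 0.272) or cell cycle (1.37, 0.341). Nor did it call anti-inflammatory mediators (−0.44, 0.978), matrix remodelling (−0.39, 0.986), mechanotransduction (−0.61, 0.0715), wounded keratinocyte (2.35, 0.135), nuclear retained RNA (−0.68, 0.383), apoptosis (−0.08, 0.296, direction up) or neutrophil activation (0.65, 0.0789). The test direction and the median differ in sign for the cytokine, neuropeptide and apoptosis lists.

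The count of 41 from edgeR with the donor block was 107 without it (30 shared), 85 with RLE factors (41 shared, 3 rises) and 79 with DESeq2 (24 shared, 2 rises). RLE moved the median of all genes, −0.22, by 0.12. The count was 0 without replicate 1 (chronic) or replicate 2 (chronic) and 71 without replicate 4 (acute). It was 711 without the acute libraries after treatment, a fit added after seeing the data, where all 41 remained. Only the chronic pairs carry a contrast in that fit. It is thus a fit of the chronic comparison, and does not test the result over all donors.

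In chronic donors 539 genes changed after treatment, 58 up and 481 down. Without the donor block 0 passed as up and 92 as down, and DESeq2 gave 9 up and 204 down. Of 34 values of named genes in chronic donors, 28 lost the call without the block. Fibre genes made up the clearest group. Of 12 slow fibre genes, 10 fell (12 when adjusted over the list alone; median −2.31, camera adjusted p = 1.59e-15, 0.511 with an estimated correlation), including CASQ2 (−4.49, SE 0.60), the light chain gene MYL3 (−2.79, SE 0.46) and the troponin genes TNNT1 (−2.75, SE 0.59) and TNNI1 (−2.28, SE 0.50). Of 12 fast fibre genes, 10 fell (11 adjusted over the list alone; median −2.81, camera adjusted p = 1.99e-14, 0.511 with an estimated correlation), including the heavy chain gene MYH1 (−4.00, SE 0.56), MYBPC2 (−3.14, SE 0.46), the calcium pump gene ATP2A1 (−2.98, SE 0.46) and CASQ1 (−2.90, SE 0.50). In the injury and regeneration list 5 of 13 fell, among them CSRP3 (−2.11, SE 0.43) and the atrophy-linked ubiquitin ligase genes FBXO32 (−2.0, SE 0.45) and TRIM63 (−3.53, SE 0.91), and camera called it lower (median −1.67, adjusted p = 0.0158, 0.636 with an estimated correlation). MYH1 went from 426.0 and 1159 CPM to 98.8 and 23.4 CPM in replicates 1 and 2. Of the 481 falls, 173 marked myonucleus-like, 103 pericyte or smooth muscle-like and 77 endothelial-like nuclei (log2 fold above 1 in that class), against 353, 247 and 419 of 15692 tested genes. Of the 58 rises, 21 marked fibroblast-like nuclei, against 195 of tested genes.

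Connective tissue genes moved in both directions in chronic donors, and the vessel genes that passed fell. In the matrix list 1 of 24 genes rose, COL1A1, the main collagen chain (2.31, SE 0.61, n = 2 pairs, edgeR Benjamini-Hochberg adjusted p = 0.00650), and 1 fell, the basement membrane collagen COL15A1 (−1.79, SE 0.41). Adjusted over the list alone 4 were higher and 1 lower (median 0.32, camera adjusted p = 0.00392, 0.511 with an estimated correlation). COL1A1 was at 274.6 and 427.2 CPM before and 4212 and 752.0 CPM after treatment, so replicate 1 holds most of the rise. Values for COL3A1 (1.78, SE 0.58) and fibronectin FN1 (1.34, SE 0.47) did not pass. In matrix remodelling (median 0.39, camera adjusted p = 0.0158, direction up, 0.511 with an estimated correlation) the collagen cross-linking enzyme LOXL2 rose (1.39, SE 0.40) and the protease gene ADAMTS9 fell (−2.35, SE 0.52). TGM2 fell to 2 UMIs, a pooled level 59.3-fold lower (95% counting interval 16.3 to 492). The endothelial genes FLT1 (−2.04, SE 0.47) and EPAS1 (−1.63, SE 0.46) and the vessel growth factor gene ANGPT1 (−1.40, SE 0.44) fell, 3 of 19 angiogenesis members, a list that camera did not call (adjusted p = 0.115). In lipid metabolism the droplet protein gene PLIN1 (−2.02, SE 0.44) and the lipase gene LPL (−1.42, SE 0.44) fell, 2 of 20 members (median −0.82, camera adjusted p = 0.0313, 0.604 with an estimated correlation).

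Of the 20 tested pain receptor and ion channel genes, 1 rose and 3 fell in chronic donors. PIEZO2, a mechanically gated channel of touch, rose (1.35, SE 0.40, edgeR Benjamini-Hochberg adjusted p = 0.0269). The potassium channel gene KCNQ5 (−3.41, SE 0.47, adjusted p = 3.25e-10), the sodium channel gene SCN7A (−3.34, SE 0.84) and the neurotrophin receptor gene NTRK2 (−1.33, SE 0.42) fell in the same edgeR test with Benjamini-Hochberg adjustment. Pooled over libraries, among the named classes KCNQ5 was highest in myonucleus-like (893 CPM), SCN7A in Schwann cell-like (827), PIEZO2 in fibroblast-like (279) and NTRK2 in adipocyte-like nuclei (460), and RAMP1, named below, in myonucleus-like nuclei (79.9). Whole-library values do not separate changes in class shares from changes within a class. Camera did not call this list (adjusted p = 0.5, mean −0.38 against a median of 0.33). In the neuropeptide, opioid and neurotrophin list 3 of 15 fell (median −0.91, camera adjusted p = 0.0158, 0.511 with an estimated correlation), among them RAMP1, part of the receptor for calcitonin gene-related peptide (−2.69, SE 0.79), whose value turned to 1.95 without replicate 2. The RAMP1 call was lost without the block (edgeR adjusted p = 0.342) and with DESeq2 (adjusted p = 0.958). HSPA8 (−1.51, SE 0.42) and HSPB1 (−1.42, SE 0.45) fell among 17 heat shock genes (median −0.54, camera adjusted p = 0.0158, 0.511 with an estimated correlation), and the filament-binding gene FLNC fell (−1.64, SE 0.42). The immediate early gene FOSB kept 1 UMI after treatment (pooled level 19.2-fold lower, 95% counting interval 3.33 to 770), and 57 of its 67 UMIs before treatment came from replicate 1. KRT1, a keratin of upper epidermis, rose (5.06, SE 1.18, adjusted p = 0.00120 in edgeR with Benjamini-Hochberg adjustment) from 0 and 4 to 8 and 33 UMIs. Camera further called mitochondrially encoded genes lower (median −0.97, adjusted p = 4.84e-08, 0.511 with an estimated correlation), and anti-inflammatory mediators (median 0.40, adjusted p = 0.0101) and nuclear retained RNA (median 0.33, 0.0345) higher, both at 0.511 with an estimated correlation, with 0 members passed in each. MEG3, in the latter list, had a value of 1.31 (SE 0.44). The cytokine list (mean −0.11) and mechanotransduction (mean −0.16) had means below 0 against a test direction of up, and were not called.

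Falls of muscle genes also appeared inside other classes of the chronic libraries, in fits added after seeing the data. In fibroblast-like nuclei 37 genes fell and none rose (0 without the block, where 289 had an unadjusted edgeR p under 0.05). They included the smooth muscle myosin MYH11 (−4.87, SE 0.55, n = 2 pairs, edgeR Benjamini-Hochberg adjusted p = 0.00503), the filament protein DES (−3.81, SE 0.44), MYH1 (−3.92, SE 0.53), myoglobin MB (−3.13, SE 0.43), the slow myosin MYH7 (−2.92, SE 0.40) and TNNC1 (−3.07, SE 0.44). In macrophage or monocyte-like nuclei 8 genes fell and none rose (0 without the block, 164 at an unadjusted p under 0.05), with MYH11 (−5.28, SE 0.95), CARMN (−3.71, SE 0.88), RGS6 (−3.70, SE 0.87), MUSTN1 (−3.40, SE 0.83), SYNPO (−3.87, SE 0.97) and TNNI1 (−2.59, SE 0.65) among them. In chronic donors the count of 539 was 92 without the block (92 shared), 213 with DESeq2 (211 shared) and 92 without replicate 2, with 57 shared.

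In acute donors 3035 genes changed, 1431 up and 1604 down, in libraries with only 79 and 138 kept nuclei after treatment. MALAT1 made up 0.408% and 0.551% of kept UMIs there, against at least 1.13% in the other libraries, and 0 and 6 of the nuclei were fibroblast-like. Loss of tissue RNA can therefore not be separated from a response in the falls below. Matrix genes fell together. Of 24 tested, 19 fell and none rose (22 adjusted over the list alone; median −2.05, camera adjusted p = 2.41e-07, 0.463 with an estimated correlation), including fibrillin FBN1 (−3.39, SE 0.68, n = 2 pairs, edgeR Benjamini-Hochberg adjusted p = 9.52e-05), the collagen genes COL5A1 (−3.40, SE 0.69) and COL6A3 (−2.64, SE 0.59) and the proteoglycan gene BGN (−3.13, SE 0.68). Of 24 mechanotransduction genes 13 fell, with the actin cross-linker FLNA (−2.62, SE 0.58) among them (median −1.76, −1.71 with genes at 0 set to their bound, camera adjusted p = 9.07e-05, 0.463 with an estimated correlation). YAP1, a growth regulator, kept 2 UMIs (pooled level 10.1-fold lower, 95% counting interval 2.78 to 83.1). In matrix remodelling 6 of 17 fell, such as the hyaluronan receptor CD44 (−3.01, SE 0.66) and the protease gene ADAMTS5 (−2.72, SE 0.66), and the median was −1.86, or −1.45 at the bound (camera adjusted p = 0.00779, 0.463 with an estimated correlation). Of 12 slow fibre genes 10 fell, with TNNI1 (−2.63, SE 0.55), TPM3 (−2.65, SE 0.56), MYL2 (−2.66, SE 0.59) and TNNT1 (−2.54, SE 0.59). Of 12 fast fibre genes 6 fell, with MYLPF (−2.30, SE 0.54) and MYL1 (−2.26, SE 0.55). Their medians were −2.35 and −1.76 (−2.33 and −1.5 at the bound), with camera adjusted p = 1.18e-04 and 0.0116, both 0.463 with an estimated correlation.

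Nuclear RNAs moved apart in acute donors. Of 9 in the list 5 fell and 1 rose (median −1.70, camera adjusted p = 0.00642, 0.463 with an estimated correlation). NEAT1, a scaffold of nuclear paraspeckles, fell (−2.76, SE 0.68), and PVT1 rose (1.86, SE 0.52). The call of PVT1 was lost without the block and with no low-count filter (edgeR adjusted p = 0.0672 and 0.212). MEG3 kept 2 UMIs, a pooled level 34.4-fold lower (95% counting interval 9.53 to 284). Falls also included PDGFRB, a pericyte receptor (−2.75, SE 0.68), SMAD3, a mediator of transforming growth factor signals (−2.40, SE 0.66), and HSPB1 (−2.04, SE 0.54). JUND (2 UMIs), KLF6 (1 UMI) and FABP4 (1 UMI) were lower by pooled ratios of 15.7-fold (4.33 to 129), 15.7-fold (2.82 to 622) and 10.3-fold (1.85 to 408; 95% counting intervals). Of the 20 tested pain receptor and ion channel genes, 2 rose and 1 fell. The ion channel gene TRPM3 (2.95, SE 0.61) and the potassium channel gene KCNQ3 (3.14, SE 0.91) rose, as did the mu opioid receptor gene OPRM1 (3.45, SE 1.18), on 8 and 10, 7 and 3, and 2 and 4 UMIs in the libraries after treatment, and the channel gene TRPM7 fell (−1.64, SE 0.61). The pain list was not called by camera (adjusted p = 0.22) but was by fry (adjusted p = 0.0471), and the neuropeptide and opioid list was called higher with 1 member up and 1 down (median 0.93, adjusted p = 0.0478, 0.463 with an estimated correlation). Camera also called lower heat shock (6 of 17 fell, median −2.04 or −1.51 at the bound), anti-inflammatory (4 of 15, −1.46 or −1.07), antigen presentation (4 of 19, −2.74 or −0.78), angiogenesis (5 of 19, −1.71 or −1.09) and lipid genes (4 of 20, −1.32 or −0.91). Cell cycle (0 of 7 passed, median 1.83, mean −0.69) and neutrophil genes (1 of 5 rose, median 2.08, mean −1.08) were called higher although their means lay below 0. All of these had adjusted p between 0.00779 and 0.0431, and 0.463 with an estimated correlation.

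The rises were of long genes: the 1431 genes that rose spanned a median of 122 kb of genome, the 1604 that fell 59.2 kb and all tested genes 43.4 kb. UMIs of genes over 500 kb made up 11.2% and 13.6% of the acute libraries after treatment and 5.70% to 8.25% of the other libraries, over all deposited barcodes. Cluster 8, without a class name, held 63.3% (52.3 to 73.1) and 72.5% (64.5 to 79.2) of the nuclei kept there.

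**Figure D3:**
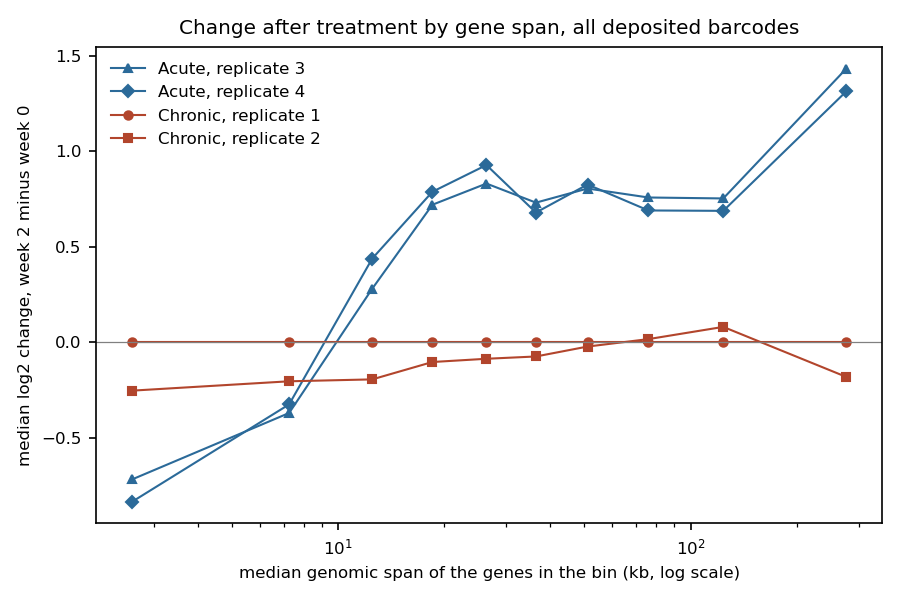
Median log2 change after treatment (vertical axis) of genes in 10 bins of genomic span (horizontal axis, kb, log scale), one line per donor, all deposited barcodes. In acute replicates 3 and 4 the medians rise from −0.72 and −0.84 in the bin of shortest genes to 1.43 and 1.31 in the bin of longest genes, and in chronic replicates 1 and 2 they stay between −0.25 and 0.08. In chronic replicate 1 every bin has a median of 0.003, the value of genes with equal or no UMIs in both libraries. Its flat line thus says little about length.

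The median of all genes in the acute comparison was −0.86 and moved by 0.38 with RLE factors, which called 2234 genes (1541 up, 693 down), while DESeq2 called 2128 (1842 up, 286 down). The count was 1853 without the block, 1683, 1397 and 184 without replicates 2, 3 and 4, 20 after thinning, 0 with at least 500 genes per nucleus, which left 3 nuclei in each acute library after treatment, and 15235 over all deposited barcodes, which shared 2821 of the 3035 in the same direction.

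The change after treatment differed between conditions for 2580 genes, 1146 with a higher and 1434 with a lower change in chronic donors. The photoreceptor gene EYS (ENSG00000188107) had the smallest p (log2 difference −5.36, SE 0.67, n = 2 pairs each, edgeR Benjamini-Hochberg adjusted p = 2.44e-11), at 66.3 and 62.4 CPM before and 18.3 and 26.8 CPM after treatment in chronic donors and 43.1 and 25.3 before and 431.5 and 594.3 CPM after in acute donors. The heparanase-like gene HPSE2 (−6.25, SE 0.81), the adhesion genes OPCML (−6.40, SE 0.83) and CNTNAP2 (−4.70, SE 0.63), and the complement regulator gene CSMD1 (−4.71, SE 0.63) differed in the same direction. So did NKAIN3 (−5.51, SE 0.79), the glypican gene GPC5 (−4.89, SE 0.72) and the noncoding CCDC26 (−5.55, SE 0.82). MEG3 differed in the other direction (6.47, SE 0.93). Rises in the acute libraries after treatment enter the lower values here. For those rises, reads over genes that the tissue does not express, taken up below, cannot be separated from a response.

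By list, 17 of 24 matrix genes had a higher change in chronic donors and none a lower one (camera adjusted p = 3.08e-08, 0.512 with an estimated correlation), with FBN1 (4.50, SE 0.88), COL5A1 (4.19, SE 0.82), COL1A1 (4.16, SE 0.89) and FN1 (3.70, SE 0.79). The median of this list was −2.05 in acute and 0.32 in chronic donors, so the difference carries the limit given for the acute falls. Camera also called higher mechanotransduction (7 of 24, adjusted p = 7.77e-04), nuclear retained RNA (3 of 9, 0.00233), anti-inflammatory (5 of 15, 0.0033) and matrix remodelling genes (5 of 17, 0.00354), and lower the neuropeptide list (1 of 15 lower, 0.0175), all at 0.709 with an estimated correlation. The test direction and the median differed in sign for the pain list (down, median 0.70) and the injury list (down, median 0.24), which were not called. The fast and slow fibre lists were not called by camera (adjusted p = 0.262 and 0.997), although MYBPC2 (−3.01, SE 0.67), MYH1 (−3.07, SE 0.77) and CASQ2 (−3.62, SE 1.01) fell further in chronic donors. The value of CASQ2 shrank to −1.15 without replicate 2 and −1.51 without replicate 3. Its call was lost without the block (edgeR adjusted p = 0.0776) and with DESeq2 (adjusted p = 0.0677). KCNQ5 (−3.32, SE 0.71) and TRPM3 (−3.14, SE 0.80) differed as well. TRPM3 was among the acute rises and carries the limit given for them. The median of all genes was 0.85 and moved by −0.42 with RLE factors, with 2118 genes (529 higher, 1589 lower), and DESeq2 gave 1552 (190 higher, 1362 lower). The count was 1284 without the block, 378, 1367 and 359 without replicates 2, 3 and 4, 14 with at least 500 genes per nucleus (3 nuclei in each acute library after treatment) and 10345 over all deposited barcodes, which shared 2333.

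**Figure D4:**
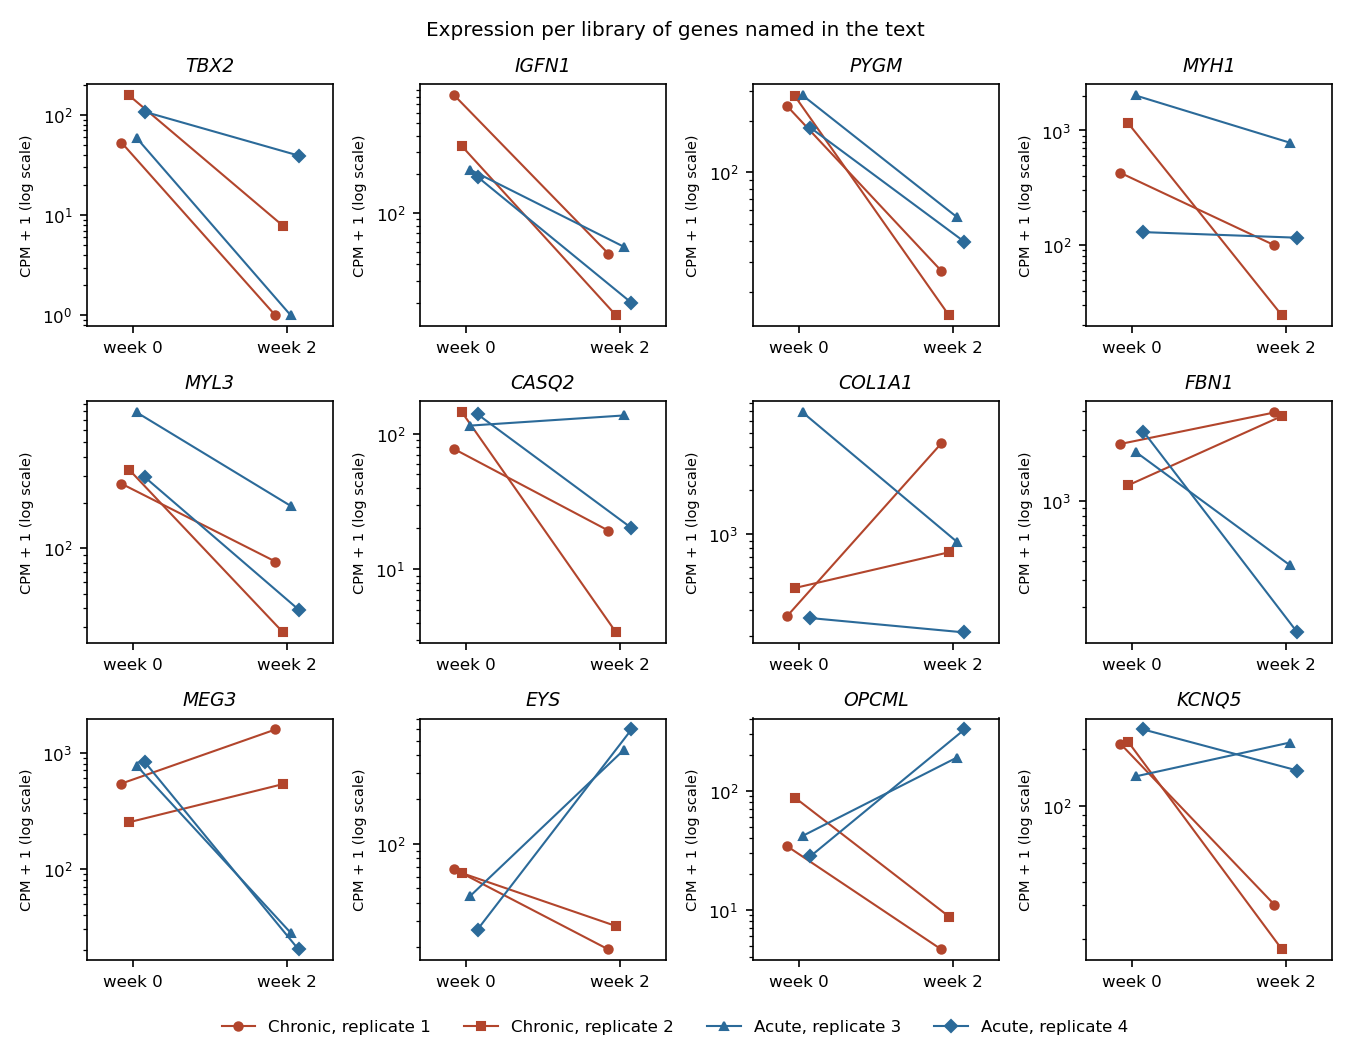
CPM + 1 (vertical axes, log scale) of 12 genes at week 0 and week 2, one line per donor, chronic in red and acute in blue. TBX2, IGFN1, PYGM and MYL3 are lower at week 2 in all 4 numbered pairs, while EYS and OPCML are lower in chronic and higher in acute donors.

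Before treatment no gene differed between chronic and acute donors by edgeR with Benjamini-Hochberg adjustment, with 310 of 15692 at an unadjusted p under 0.05 and 2 called by DESeq2. Among the lower values of smallest p in chronic donors were those of ACTC1, the cardiac actin (−5.94, SE 1.45, n = 2 against 2), MYBPH, a myosin-binding protein (−6.71, SE 1.64), and the embryonic myosin MYH3 (−3.89, SE 1.02), with S100A1 (−2.24, SE 0.50) and the lipid carrier APOE (−2.36, SE 0.52). Among the higher values of smallest p were those of GPM6A, a neuronal membrane protein (2.67, SE 0.58), and WFDC2, an epithelial protein (4.24, SE 1.00). ANKRD30BL (2.68, SE 0.60), POTEG (3.44, SE 0.79) and MTRNR2L1 (2.63, SE 0.62) have near-identical copies, so their counts are uncertain. Camera called 7 of the 24 lists lower in chronic donors. The injury and regeneration list had 4 of 13 members lower when adjusted over the list alone, MYH3, ANKRD1 (−2.81, SE 0.88), NCAM1 (−1.35, SE 0.43) and MYH8 (−4.12, SE 1.43; median −1.19, camera adjusted p = 9.63e-05, 0.619 with an estimated correlation). Slow fibre genes had 1 of 12 lower over the list alone, MYOZ2 (−1.80, SE 0.54; median −0.68, camera adjusted p = 4.28e-04, 0.619 with an estimated correlation). Mechanotransduction (−0.32, 4.28e-04), matrix (−0.46, 0.00166), matrix remodelling (−0.29, 0.00255), fast fibre (−0.75, 0.00297) and anti-inflammatory genes (−0.31, 0.00778) had 0 members passed over all genes or over the list alone, and adjusted p of 0.27 to 0.746 with an estimated correlation. Immediate early genes had a median of 0.44 against a test direction of down (camera adjusted p = 0.801), and FOS (4.42, SE 1.21) rested on 544.4 CPM in chronic replicate 1 against 5.69 in replicate 2, and was −1.09 without replicate 1.

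Inside myonucleus-like nuclei before treatment, 6 genes differed in an added fit, MYBPH (−6.09, SE 0.76, n = 2 against 2, edgeR Benjamini-Hochberg adjusted p = 0.00127), ACTC1 (−5.55, SE 0.70), PRUNE2 (−3.51, SE 0.56), the adhesion gene NCAM1 (−3.12, SE 0.57) and the stress-responsive ANKRD1 (−3.13, SE 0.57) lower in chronic donors and LRP1B (2.57, SE 0.44) higher. MYBPH was at 0 and 3.76 CPM in chronic replicates 1 and 2, and at 314 and 201 CPM in acute replicates 3 and 4. Chronic replicate 1 held only 37 such nuclei, and ACTC1, PRUNE2 and NCAM1 were at 0 there too. The sizes of these folds are therefore uncertain. Endothelial-like nuclei gave 3 genes, with ACTC1 (−5.34, SE 0.88) and LINC02315 (−4.28, SE 0.78) lower. LINC02315 was at 14.0 and 311 CPM in acute replicates 3 and 4 and 0 and 8.55 in chronic replicates 1 and 2, so 1 library carried it. ACTC1 was at 262 and 19.6 CPM in the acute and 0 and 3.21 in the chronic replicates. Whether muscle RNA in endothelial-like droplets gave the ACTC1 difference was not tested. Adipocyte-like nuclei gave 3 genes, with COL1A1 (−3.49, SE 0.66) and APOE (−2.77, SE 0.61) lower. Without acute replicate 3 the value of COL1A1 in adipocyte-like nuclei was 1.37. Fibroblast-like and macrophage-like nuclei gave 0 by edgeR, with 244 and 47 genes at an unadjusted p under 0.05, and DESeq2 was not run within classes. In endothelial-like and adipocyte-like nuclei, as in myonucleus-like ones, a fit with 1 library left out takes its spread from the group of 2 alone. The counts of such fits, given below, do not show how stable the genes are. The whole-library count of 0 became 8, 27 and 26 without chronic replicate 1, chronic replicate 2 and acute replicate 4, and 40 with no low-count filter. The myonucleus count of 6 was 42, 0, 20 and 36 without chronic replicate 1, chronic replicate 2, acute replicate 3 and acute replicate 4, in fits of 1 library against 2 whose spread comes from the group of 2 alone, so these counts do not show how stable the 6 genes are. Without chronic replicate 1, chronic replicate 2 and acute replicate 4 the endothelial count of 3 was 0, 0 and 8 and the adipocyte count of 3 was 1, 6 and 13, and the fibroblast count of 0 was 2 without chronic replicate 2.

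After treatment 2099 genes differed, 814 higher and 1285 lower in chronic donors. Lower in chronic donors were EYS (−4.43, SE 0.53, n = 2 against 2, edgeR Benjamini-Hochberg adjusted p = 0.00118), NKAIN3 (−5.23, SE 0.64), OPCML (−5.25, SE 0.69), the netrin receptor gene DCC (−4.45, SE 0.59), and CSMD1 (−3.82, SE 0.51). Also lower were the glutamate receptor gene GRM7 (−4.22, SE 0.59), AGBL4 (−4.00, SE 0.57), RALYL (−5.19, SE 0.75), DPP10, a potassium channel partner (−3.93, SE 0.58), and SOX2-OT (−3.79, SE 0.53), a transcript that overlaps another gene. Rises in the acute libraries after treatment can enter these lower values, so the limit given above for such rises holds here too. Higher in chronic donors were SEMA3C, a secreted guidance protein (4.30, SE 0.75), and CD44 (3.52, SE 0.66). In acute donors after treatment RAP1B and USP53 had 1 UMI, MEG3 and TTC3 had 2, and ARHGAP21 had 3. Their pooled levels in chronic donors were higher by 34.3-fold (95% counting interval 6.15 to 1360), 34.3-fold (6.14 to 1360), 29.3-fold (8.09 to 242), 13.5-fold (3.71 to 111) and 16.2-fold (5.54 to 78.7). PPP1R12A and DYNC1I2 passed as higher in chronic donors, with 0 UMIs in acute donors after treatment.

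The matrix list had 7 of 24 members higher in chronic donors after treatment (14 adjusted over the list alone, median 2.11, camera adjusted p = 5.03e-06, 0.523 with an estimated correlation), among them FBN1 (3.93, SE 0.82), FN1 (4.03, SE 0.87) and COL5A1 (3.97, SE 0.89). The limit given for the acute falls holds for this list too. Camera also called higher nuclear retained RNA (3 of 9, with NEAT1 at 3.19, SE 0.81; median 2.03, adjusted p = 0.00265, 0.236 with an estimated correlation), mechanotransduction (3 of 24, median 1.49 or 1.45 at the bound, 0.00265, 0.236) and anti-inflammatory genes (2 of 15, 1.54 or 1.35, 0.0256, 0.606), and lower the neuropeptide list (1 of 15 lower, median −1.55, 0.0312, 0.606). VCL, of cell adhesions, was among the higher mechanotransduction genes, with 3 UMIs in acute donors (pooled ratio 6.16, 95% counting interval 2.10 to 30). In the pain list 5 of 20 were lower, with KCNQ5 (−3.14, SE 0.62) and SCN7A (−5.13, SE 0.97), and 1 was higher, and camera did not call it (adjusted p = 0.296, direction down against a median of 0.38, or 0.04 at the bound), while fry did (adjusted p = 0.00631). The median of all genes was 0.78 and moved by −0.38 with RLE factors, which gave 343 higher and 1383 lower genes, while DESeq2 gave 268 and 1801. The count was 3567, 348 and 0 without chronic replicate 1, chronic replicate 2 and acute replicate 4, 0 with at least 500 genes per nucleus (3 nuclei in each acute library), and 13076 over all deposited barcodes, which shared 1934.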

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

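The tests for nuclei of neurons, for too few UMIs, for muscle RNA in other nuclei, for depth and for chance sharing of barcodes were chosen only after the result was seen, and those for gene length, for genes of unrelated tissues and for reads of one library in the other before it.

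The change after treatment differed between chronic and acute donors for 2580 genes and 6 gene lists in a test of the difference itself. Lower changes in chronic donors were found for EYS (−5.36), HPSE2 (−6.25), OPCML (−6.40), CNTNAP2 (−4.70), CSMD1 (−4.71), NKAIN3 (−5.51), GPC5 (−4.89), CCDC26 (−5.55), MYBPC2 (−3.01), MYH1 (−3.07), CASQ2 (−3.62), KCNQ5 (−3.32) and TRPM3 (−3.14). Of these, CASQ2 was −1.15 without replicate 2 and −1.51 without replicate 3. Higher changes were found for MEG3 (6.47), FBN1 (4.50), COL5A1 (4.19), COL1A1 (4.16) and FN1 (3.70). A signal also appeared in barcodes that the comparisons left out. Over all deposited barcodes, 23 genes of unrelated tissues summed to 115 and 135 CPM in the acute libraries after treatment, against 8.69 and 4.99 before. In the chronic libraries they summed to 47.1 and 15.3 before and 3.37 and 10.3 CPM after. Chronic replicate 2 and acute replicate 4 after treatment shared 342 barcodes.

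In the acute libraries after treatment 1431 genes rose, with TRPM3 and KCNQ3 among them. Too few UMIs in kept barcodes were argued against as the whole cause, since all 1431 rises were higher over all deposited barcodes too, with a median log2 of 4.6. Genes of unrelated tissues, which should be silent here, moved by a median of 3.19 (SD 1.69, 22 of 23 higher), which is consistent with reads spread over genes that the tissue does not express; many of these genes had few or no UMIs, so the added 0.5 count weighs on this median, but not on the summed CPM above, which were added after it was seen. Gene length stays open (lower Spearman rho across genes 0.212, against 0.023 and 0.042 in chronic pairs, with genes not independent). In chronic replicate 1 the median change was 0.003 in every span bin, as for equal or no UMIs, so its rho is a weak comparator. Nuclei of neurons stay open too, under a criterion made stricter after their median of 1.72 was seen. Of 13 compact neuronal genes 9 were higher (SD 2.84), but their summed CPM went from 456 to 171 and from 123 to 157. A response of acute donors to treatment, the biological explanation that the design names, was not tested apart from these and stays open. The 1604 falls in these libraries were not tested for a technical cause.

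In the chronic libraries after treatment, muscle genes fell. A difference in depth was argued against as the whole cause. The muscle fibre lists had a median log2 of −1.52 in replicate 1, whose total UMIs in kept nuclei after treatment were 1.28 times those before. Their median was −3.53 in replicate 2, whose nuclei had near equal depth (medians of 337 and 338 UMIs). Neither pair was matched in both. Inside fibroblast-like nuclei the same lists had a median of −2.65, with 22 of 22 members below 0, so less free muscle RNA in all droplets may account for part of the falls. The observed myonucleus-like share was also lower in these donors, by logits of −0.446 and −4.04, so needle position or depth of sampling cannot be separated from an effect of treatment, and a response of muscle to treatment stays open and untested.

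The 342 shared barcodes were 6.82 times the number expected from the library pairs with the most possible matches (50.1), which argues against chance. Of the 28 pairs, 4 others shared more than expected (Poisson, Benjamini-Hochberg adjusted p from 6.61e-08 to 0.0379): acute replicate 4 after treatment with chronic replicate 1 before (23, 4.55 times) and after treatment (11, 10.1 times), and acute replicate 3 after treatment with acute replicate 4 before (179, 1.51 times) and chronic replicate 1 after treatment (8, 2.95 times). In the acute library these barcodes had a MALAT1 share of 2.67%, near the 2.70% of the same barcodes in the chronic library and above the 0.193% of its other barcodes, which is consistent with reads of the chronic library in the acute one. They had a median of 28 UMIs there, and 2 of them were kept, so the comparisons held few of them. No biological explanation was tested.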

How the results depend on the processing

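The settings chosen after seeing the data were those without the acute libraries after treatment, all fits within classes, and the list tests and their alternatives within chronic donors, within acute donors and for their difference; for each departure below the cause was not tested, except that thinning and the limit of 500 genes leave fewer UMIs. For treatment over all donors, 41 genes became 85 with RLE factors, 79 with DESeq2, 325 with at least 500 genes, and 0 with no low-count filter, with all deposited barcodes and with thinning. Without the acute libraries after treatment the count was 711, in a fit that rests on the chronic pairs alone. The count of 539 in chronic donors became 213 with DESeq2 and 32 with thinning. Here and below, thinning left 486 genes to test against 15692, so its counts are not on the same scale. In acute donors 3035 became 0 with at least 500 genes, 15235 with all barcodes and 20 with thinning. The difference of changes went from 2580 to 1552 with DESeq2, 14 with at least 500 genes, 10345 with all barcodes and 28 with thinning. Before treatment 0 became 2 with DESeq2 and 40 with no low-count filter. After treatment 2099 became 3566 with no low-count filter, 0 with at least 500 genes, 13076 with all barcodes and 33 with thinning. Without the replicate block the counts were 107, 92, 1853 and 1284 for all donors, chronic donors, acute donors and their difference, and 0 in fibroblast-like and 0 in macrophage-like nuclei. Leaving out 1 donor or library gave 0 to 71 for all donors, 92 to 701 for chronic, 184 to 2743 for acute, 359 to 2151 for the difference, 0 to 27 before and 0 to 3567 after treatment. Within classes before treatment it gave 0 to 2 in fibroblast-like, 0 to 8 in endothelial-like, 0 to 42 in myonucleus-like (fits of 1 library against 2 with spread from the group of 2 alone), 1 to 13 in adipocyte-like and 0 to 0 in macrophage-like nuclei, and RLE factors gave 0 in adipocyte-like nuclei. The endothelial-like and adipocyte-like counts carry the same limit as the myonucleus-like ones. The lists called (10, 11, 14, 6, 7 and 5 for all donors, chronic, acute, their difference, before and after) all became 0 with an estimated correlation. With fry the counts were 0, 0, 7, 0, 0 and 3, in part of other lists: of the 7 in acute donors, camera had not called the pain, keratinocyte differentiation and wounded keratinocyte lists, and of the 3 after treatment it had not called the pain list. Leaving out a donor gave 10 to 15 for all donors.

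Mean logit changes of class shares left out 1 donor at a time spanned −0.743 to 1.5 for fibroblast-like (−0.743 without replicate 2), −2.03 to −1.32 for pericyte or smooth muscle-like, −1.17 to −0.310 for endothelial-like, −2.53 to −1.33 for myonucleus-like, 0.547 to 1.3 for macrophage-like, −1.19 to 0.530 for adipocyte-like (0.530 without replicate 1) and −1.13 to 1.15 for Schwann cell-like nuclei (1.15 and 0.158 without replicates 2 and 4). With at least 500 genes, and 3 nuclei in each acute library after treatment, they were −0.871 for pericyte or smooth muscle-like, −0.648 for myonucleus-like, 1.89 for macrophage-like, 0.323 for adipocyte-like and 1.25 for Schwann cell-like nuclei, the last of which was 1.92 with no mitochondrial limit. Kept nuclei were 18166 with at least 500 genes and 121029 with no mitochondrial limit. Fibroblast-like nuclei were not named at resolution 1.0, nor pericyte and endothelial-like nuclei with no mitochondrial limit, so these have no value, and the planned test within classes was not run. Of 1786 values of named genes under the alternatives, 1337 kept direction and side of the threshold, 359 lost and 80 gained the call, and 10 reversed: with at least 500 genes, where so few nuclei remain that a sign carries no information, GRM7 after treatment (7.02), HPSE2 (5.21) and CASQ2 (5.46) in the difference, PVT1 (−0.84) and KCNQ3 (−7.58) in acute donors and SCN7A after treatment (4.74); without replicate 2 RAMP1 in chronic donors (1.95; range over donors left out −4.35 to 1.95); without chronic replicate 1 FOS before treatment (−1.09; −1.09 to 5.49); and without acute replicate 3 COL1A1 before treatment, whole (0.44; −4.31 to 0.44) and in adipocyte-like nuclei (1.37; −4.53 to 1.37). Depth limits above all the acute libraries after treatment, where 1 UMI is worth 27.0 and 19.2 CPM.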

Other observations

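The count of other splits was chosen as a test only after the result was seen. It was made over 8 splits, widened to all splits, and set back to those that part all pairs after both had been seen.

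For the 41 genes called after treatment over all donors, 8 splits of the 8 libraries part all 4 pairs, too few for a share under 0.05. Of these, 2 gave as many genes, the real one and a split that reverses the direction of time between chronic and acute donors. That split gave 164, the highest of the others, which points to a structure of the samples, the difference of changes between conditions, and the next gave 4. Of the other 27 splits, 24 part 2 pairs and repeat fits in pairs of splits, with 77, 77, 92 and 92 genes in 4 of them and at most 3 in the rest, and 3 part no pair and could not be fitted with the donor as a block.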
